A study of Mus musculus with 4 samples.

How the data were processed

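The data were 4 RNA sequencing libraries of RAW 264.7 cells, 2 from cells stably carrying the empty plasmid and 2 from cells stably carrying Dnm3os. Per the labels, poly(A) RNA libraries were made from total RNA with a TruSeq kit and sequenced on a HiSeq 2500. The submitters' processing notes name TopHat, Bowtie2 and DESeq2 and the genome build mm9, with no versions and no roles. The read counter, the annotation version and the strand setting are not given in the sources used here.

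Each deposited file gives, per the file headers, raw counts and normalized counts for 35786 RefSeq transcripts. The authors' raw column holds whole-number read counts per transcript, and its values show that isoforms of a gene hold overlapping counts. The deposited normalized column is a scaled signal: it equals the raw count times 1 constant per library (0.8653, 0.9775, 1.1723 and 1.0058 in empty vector 1, empty vector 2, Dnm3os 1 and Dnm3os 2), which was checked on every transcript. The raw counts were used throughout, and the normalized column served only for its constants, as an alternative scaling.

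Transcripts were named from a RefSeq table (35494) and a GENCODE table (183), which left 109 unnamed with 0.246 to 0.276% of the counts. Of the 24422 named genes, 6123 had more than 1 transcript. For each gene the transcript with the highest mean count was kept, since isoforms of a gene hold overlapping counts. This choice, with the 45S ribosomal RNA transcript removed, left out 39.4% of all counts, repeats and counts of other isoforms alike. No coordinates are given, because the reference at hand is of another build than the one in the processing notes. The 45S ribosomal RNA transcript, with 0.072 to 0.134% of the counts, was left out of the library sizes. Summed counts over all transcripts ranged from 48480628 to 65610942 per library, and over 1 transcript per gene from 29416272 to 39769640.

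Genes were filtered with filterByExpr, scaled with TMM (factors 0.9970 to 1.0030) and tested with edgeR 4.0.16 (glmQLFit with robust set, glmQLFTest) in R 4.3.3. All tests were two-sided, with Benjamini-Hochberg adjustment over the 13172 genes tested and a threshold of 0.05 on the adjusted p. Log2 fold changes are those of the edgeR fit at its default prior count, and their SE is the absolute log2 fold change over the square root of F. CPM, counts scaled to the library size, are given as group means with the SD over 2 libraries. A fold against a group with 0 counts is given as a lower bound against 3 counts over that group, and genes with 1 to 3 counts in a group are given by their counts. Such floors cover counting error only.

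Gene lists were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count of 2), with a preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way and compares it with no other genes. Adjusted p-values of lists are over the 20 lists tested. Where alternatives of a list's adjusted p are given as a range signed by direction, a minus sign stands for down. The lists were Dnm3os and its locus, cytokines and chemokines, NF-kB feedback and targets, innate sensors and inflammasome, interferon-stimulated, immediate early, phagocytic and scavenger receptors, macrophage identity, alternative activation, phagocyte oxidase and oxidative stress, lipid uptake and efflux, antigen presentation, unfolded protein response, cholesterol synthesis, osteoclast, lysosome and autophagy, histone and DNA modifiers, extracellular matrix, nucleolar and ribosome biogenesis, cell cycle, and glycolysis and hypoxia. A further 6 lists held markers of other cell types and were not tested as groups. Of the locus list 4 genes were matched and 1 could be tested, and Mir3120, H2-L, Mll2 and Trac found no match in the tables.

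The named genes were Dnm3os, Dnm3, Ncl, Ilf2, Tnf, Il6 and Il1b whatever their values, the 10 largest rises and the 10 largest falls among called genes with a mean CPM of at least 5 whose groups did not overlap, leaving out predicted genes, and up to 4 called members of each list with the smallest adjusted p. Other genes are marked as named after their values were seen. A gene is uncertain where paralogs share reads; 57 of the 10634 genes with a mean of at least 100 counts had the same 4 counts as another gene.

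The alternatives were DESeq2's size factors, upper-quartile factors or total counts in place of TMM, DESeq2 1.42.0 and limma-voom in place of edgeR, no filter and a filter at 1 CPM in 2 libraries, a replicate block, each library left out in turn, and, chosen after the data were seen, isoforms summed and the authors' scaling constants. A fit that leaves out a library assumes that the lone library of its group varies like the others. A count of genes or lists was read as similar within 1.5 times the main count. Replicates differed by more than counting error, with a chi-square per degree of freedom of 5.12 for empty vector and 4.22 for Dnm3os over genes with at least 20 counts, and the biological coefficient of variation was 3.65%.

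The procedure was tested on simulated data of the same depth and spread for 13058 genes. It recovered 68.0% of genes changed 1.25-fold, 76.0% at 1.5-fold, 85.7% at 2-fold and 100.0% at 4-fold, and 9.7% of its 195 calls were unchanged genes. Camera called the 1 raised list and fry did not, and each called 0 of 20 unchanged lists, where no other tool was run. The simulated genes were drawn independently of each other, so this cannot show how the preset correlation of 0.01 serves correlated lists. In the real lists the estimates reached 0.5713, for glycolysis and hypoxia. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.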

Results

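Poly(A) RNA of RAW 264.7 cells, a mouse macrophage line, was sequenced in 4 libraries. 2 libraries came from cells stably carrying the empty expression plasmid and 2 from cells stably carrying the same plasmid with Dnm3os, a long noncoding RNA transcribed opposite to and inside the gene Dnm3. All cells were at passages 3 to 6 in medium with 5.5 mmol/L glucose. The summed read counts over all RefSeq transcripts were 65610942 and 58557747 in empty vector libraries 1 and 2, and 48480628 and 56540814 in Dnm3os libraries 1 and 2. With 1 transcript kept per gene, the totals were 39769640, 35447766, 29416272 and 34314038 in that order, and between 12946 and 13226 genes had at least 10 counts. The series title concerns the function of Dnm3os, which it calls induced by diabetes, in macrophages. The single comparison asks which transcripts differ when the cells carry Dnm3os.

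Dnm3os itself was seen in both Dnm3os libraries, with 208 and 260 counts or 7.07 and 7.58 CPM (counts scaled to library size), a mean of 7.33 ± 0.365 (SD, n = 2). Both empty vector libraries had 0 counts, so Dnm3os was at least 184-fold higher against a floor of 3 counts over the empty vector group, which is 0.0399 CPM (adjusted p = 5.25e-14 by edgeR). That floor covers counting error alone. Its level was below that of most expressed genes, since 28.4% of the genes tested had a lower mean CPM in the Dnm3os group. The host gene Dnm3, which encodes a dynamin, had 0 counts in all 4 libraries for both of its transcripts. The microRNA genes Mir214 and Mir199a-2 lie within Dnm3os; Mir214 had 3 and 4 counts in the Dnm3os libraries and Mir199a-2 had 1 and 1, with 0 in the empty vector libraries. Counts per gene do not separate RNA made from the plasmid from RNA of the chromosomal gene.

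In cells carrying Dnm3os, Mmp12, the macrophage elastase, rose 15.1-fold, from 0.940 ± 0.0889 to 14.3 ± 0.746 CPM (SD, n = 2 per group; adjusted p = 2.15e-15 by edgeR). Ctsc, the lysosomal dipeptidyl peptidase cathepsin C, rose 6.30-fold, from 4.45 ± 0.625 to 28.0 ± 1.77 CPM (adjusted p = 4.16e-15 by edgeR). Flt1, a receptor of vascular endothelial growth factor, was 5.49-fold lower at 10.8 ± 0.525 against 59.5 ± 1.62 CPM (adjusted p = 7.35e-18 by edgeR). Ctsk, the collagen-degrading protease cathepsin K, was 2.85-fold lower at 75.1 ± 1.11 against 214 ± 9.55 CPM (adjusted p = 4e-18 by edgeR).

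The other large rises by the naming rule, as log2 fold change with SE, were Ly86, a partner of the toll-like receptor homologue Cd180 (2.40 ± 0.15), Spink5, a serine protease inhibitor (2.22 ± 0.08), and Nos2, the inducible nitric oxide synthase (2.21 ± 0.21). They were followed by Clec4n, the fungal receptor dectin-2 (2.03 ± 0.12), the chemokine Cxcl14 (1.99 ± 0.09), the semaphorin Sema4a (1.95 ± 0.13), the leukocyte surface antigen Cd52 (1.91 ± 0.07) and the glutathione transferase Gstt1 (1.90 ± 0.15). Gstt1 belongs to a family of similar genes, so its reads are uncertain. The call of Nos2 was lost with a replicate block. The largest named fall was in counts at the small nucleolar RNA gene Snora41, 86.5-fold lower at 0.551 ± 0.0372 against 47.8 ± 0.592 CPM (adjusted p = 4.37e-21 by edgeR). Whether these counts in poly(A) RNA come from the small RNA itself was not tested. The TGF-beta co-receptor Eng fell by 1.59 ± 0.09 on the log2 scale and Tacr1, the substance P receptor, by 1.48 ± 0.09. Smaller falls were those of the actin cross-linker Flnc (-1.23 ± 0.10), the zinc finger gene Zfp365 (-1.20 ± 0.11), the actin-binding Svil (-1.16 ± 0.11), Serinc2 (-1.13 ± 0.07) and the hyaluronan receptor Layn (-1.13 ± 0.07).

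In all, 858 of the 13172 genes tested were higher and 758 lower in the Dnm3os libraries by edgeR's quasi-likelihood test (two-sided, Benjamini-Hochberg adjusted p under 0.05), which is 12.3% of the genes. Most differences were small: 75.6% of the calls were under 1.5-fold, 164 genes were at least 2-fold higher and 62 at least 2-fold lower. The values of the groups did not overlap for any of the 1616 called genes, nor for 51.2% of all genes tested, where chance alone gives 33.3%. DESeq2 called 404 genes higher and 362 lower, with 98 and 40 past 2-fold, a filter at 1 CPM left 102 genes at least 2-fold higher, and the fit called 492 higher and 455 lower without Dnm3os library 1 and 465 and 396 without Dnm3os library 2. The p-values measure spread between these libraries alone, which may be technical, since the labels do not say whether the libraries of a group came from separate cultures.

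**Figure D1:**
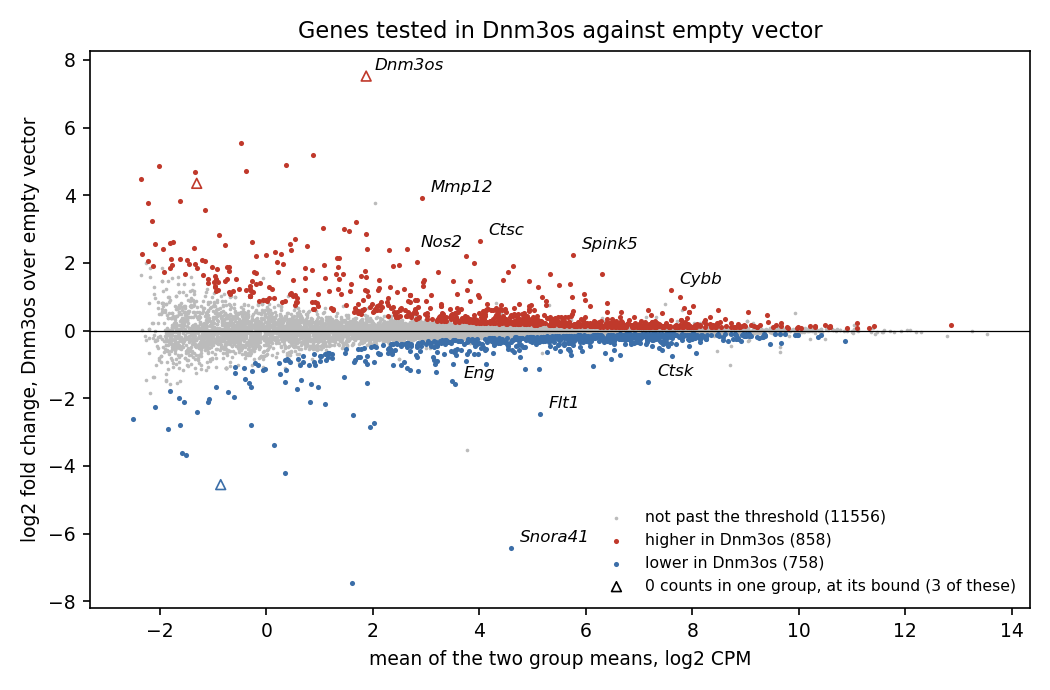
Log2 fold change of Dnm3os over empty vector against the mean of both group means in log2 CPM, 1 point per gene tested (2 libraries per group), with open triangles at the bound for the 3 genes with 0 counts in one group. Most called genes, 858 higher and 758 lower, lie close to 0, and the named genes with the largest changes stand apart at low and middle levels.

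Genes of cytokines and chemokines were higher as a group by camera with a preset correlation (adjusted p = 2.51e-07), but not called with an estimated one (adjusted p = 0.335 with an estimated correlation, the upper end of its alternatives from 3.71e-09 to 0.335). Of 30 tested members, 12 rose, 1 fell and 17 did not pass the threshold (13 higher and 2 lower adjusted over the list alone), and the median log2 fold change was 0.31. The list also held the enzymes Nos2 and Ptgs2, and Nos2 was among the members that rose. The monocyte chemokine Ccl2 rose from 195 ± 0.286 to 323 ± 13.97 CPM (0.73 ± 0.03), Tnf from 174 ± 1.08 to 216 ± 6.30 CPM (0.32 ± 0.03; adjusted p = 2.07e-07 by edgeR), and Il1b from 1.29 ± 0.379 to 4.15 ± 0.152 CPM (1.67 ± 0.19; adjusted p = 1.1e-06 by edgeR). The chemokine Ccl9 (0.45 ± 0.03) and the granulocyte colony-stimulating factor Csf3 (1.21 ± 0.10) also rose, whereas Il6 had counts of 1 and 0 in the empty vector and 1 and 6 in the Dnm3os libraries and was not tested. The scavenger receptor and chemokine Cxcl16 was the member that fell (-0.20 ± 0.06), a call lost with each of the 4 libraries left out in turn, and 0 members were lower without empty vector library 2 or Dnm3os library 2, by DESeq2 or with isoforms summed, against 2 with no filter on low counts.

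Of the 24 feedback regulators and targets of NF-kB, the inflammatory transcription factor, 7 rose, 0 fell and 17 did not pass (8 higher and 0 lower adjusted over the list alone; median 0.08). The atypical inhibitor Nfkbiz (0.66 ± 0.06), the adaptor Traf1 (0.68 ± 0.10), the feedback inhibitor Tnip3 (0.21 ± 0.04) and the survival gene Bcl2a1b (0.36 ± 0.06), whose reads may be shared with its paralogs, were among those that rose. For the 0 lower, edgeR had 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Camera gave adjusted p = 0.0226, and adjusted p = 0.335 with an estimated correlation, over alternatives from 0.0170 to 0.335. Without empty vector library 1 the list was lost (adjusted p = 0.0645 by camera) and 2 members were lower, without Dnm3os library 1 it was lost (adjusted p = 0.0595 by camera), and without Dnm3os library 2 it kept its call with 4 members higher.

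Among 25 innate sensors and inflammasome genes, 5 rose, 1 fell and 19 did not pass (7 and 2 adjusted over the list alone; median 0.02; adjusted p = 0.199 by camera). The negative regulator Irak3 (0.65 ± 0.09), the adaptor Ticam2 (0.68 ± 0.11) and the toll-like receptors Tlr2 (0.16 ± 0.03), Tlr1 (0.59 ± 0.14) and Tlr4 (0.16 ± 0.05) rose, and the inflammatory caspase Casp4 fell (-0.22 ± 0.07). Tlr1 was not called by DESeq2 or without Dnm3os library 2, and Casp4 not without empty vector library 2 or either Dnm3os library, where 0 members were lower. DESeq2 called 3 members higher and 0 lower, and with isoforms summed 0 were lower. Tlr4, at adjusted p = 0.0498 by edgeR, was called under 6 of its 14 alternatives and not without empty vector library 1 or Dnm3os library 1. The list passed without empty vector library 2 (adjusted p = 0.0333 by camera), without a filter on low counts (0.0484) and with isoforms summed (0.0424), over alternatives from 0.0333 to 0.532.

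Interferon-stimulated genes were not called as a list (adjusted p = 0.296 by camera; median -0.02). Of 40 members, 1 rose, 7 fell and 32 did not pass (4 higher and 9 lower adjusted over the list alone). The guanylate-binding Gbp3 (-0.57 ± 0.06), Oasl2 (-0.24 ± 0.03), an oligoadenylate synthetase-like gene, and the ubiquitin ligase Herc6 (-0.32 ± 0.06) fell, and Oasl1 rose (0.19 ± 0.03). When empty vector library 1 was left out, 2 members were higher, with no filter on low counts 3 were, and 4 were lower without Dnm3os library 1 and also without Dnm3os library 2. Of 20 immediate early genes, 7 rose, 3 fell and 10 did not pass (7 and 4 adjusted over the list alone; median 0.04; adjusted p = 0.411 by camera). Egr1 (0.50 ± 0.06), Jund (0.34 ± 0.05) and Klf6 (0.27 ± 0.04), all transcription factors, rose, while the AP-1 members Fosl2 (-0.34 ± 0.03), Fos (-0.23 ± 0.05) and Fosl1 (-0.20 ± 0.06) fell. DESeq2 called 4 immediate early genes higher; without Dnm3os library 2, 4 were higher and 1 was lower, with Fos and Fosl1 no longer called; Fosl1 was also lost by DESeq2 and without empty vector library 1 or Dnm3os library 1. Cxcl16, Tlr4, Casp4, Fos and Fosl1 were named after their values were seen.

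Phagocytic and scavenger receptor genes moved both ways, with more of them higher. Of 31 tested, 13 rose, 5 fell and 13 did not pass (16 higher and 6 lower adjusted over the list alone; median 0.08). Itgam, the integrin chain CD11b, was 2.01-fold higher at 290 ± 5.65 against 144 ± 9.77 CPM (adjusted p = 9.51e-12 by edgeR), and the immunoglobulin receptors Fcgr1 (0.75 ± 0.05) and Fcgr2b (0.79 ± 0.07) and the fungal receptor Clec4n rose. The members that fell were the bridging proteins Gas6 (-0.69 ± 0.14) and Mfge8 (-0.28 ± 0.05), the scavenger receptors Scarb1 (-0.19 ± 0.03) and Cd68 (-0.11 ± 0.03), and the lipid-sensing receptor Trem2 (-0.16 ± 0.03). By camera the list had adjusted p = 0.0322, and adjusted p = 0.388 with an estimated correlation, over alternatives from 0.0218 to 0.388. The list was lost without empty vector library 1 (adjusted p = 0.0743 by camera) and without Dnm3os library 1 (adjusted p = 0.0843 by camera), and the call of Cd68 was lost without empty vector library 1 or either Dnm3os library.

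Macrophage identity genes were higher as a list (median 0.14; adjusted p = 0.000374 by camera, and adjusted p = 0.335 with an estimated correlation, over alternatives from 0.000299 to 0.335). Of 21 members, 6 rose, 2 fell and 13 did not pass (8 and 2 adjusted over the list alone). The growth factor receptor Csf1r (0.27 ± 0.03) and the transcription factor Irf8 (0.62 ± 0.07) rose with Itgam, and Adgre1, the macrophage marker F4/80 (-0.30 ± 0.04), fell with Cd68. The members lower numbered 1 without empty vector library 1, Dnm3os library 1 or Dnm3os library 2. Of 13 tested alternative activation genes, 3 rose, 0 fell and 10 did not pass (3 and 0 adjusted over the list alone; 1 higher by DESeq2; median 0.01; adjusted p = 0.411 by camera), and for the 0 lower edgeR had 0 at an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. The inhibitory receptor Cd200r1 (0.74 ± 0.09), the chemokine Ccl22 (1.17 ± 0.32) and the transcription factor Klf4 (0.30 ± 0.09) rose. Without empty vector library 1, and also without Dnm3os library 2, 1 of these was called, since both settings lost Ccl22 and Klf4; Klf4 was lost with each of the 4 libraries left out in turn and with isoforms summed, and DESeq2 called neither Ccl22 nor Klf4.

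Genes of the phagocyte oxidase and of oxidative stress included Cybb, its catalytic subunit, which was 2.30-fold higher at 270 ± 8.20 against 118 ± 5.89 CPM (adjusted p = 1.81e-15 by edgeR). Of 21 tested, 8 rose, 3 fell and 10 did not pass (10 and 5 adjusted over the list alone; median 0.07). The small GTPase Rac2 (0.27 ± 0.03) and the peroxidase Prdx1 (0.13 ± 0.02) rose, and the heme oxygenase Hmox1 (-0.33 ± 0.05), the stress transcription factor Nfe2l2 (-0.13 ± 0.03) and the reductase Txnrd1 (-0.10 ± 0.03) fell. The list had adjusted p = 0.116 by camera, and fry, which asks whether a list moves on balance one way, adjusted p = 0.0366, over alternatives from 0.0366 to 0.532. The members higher were 4 without empty vector library 1, 5 without Dnm3os library 1 and 3 without Dnm3os library 2, and 1 was lower without either Dnm3os library. DESeq2 called 4 higher and 1 lower, and 5 were lower with upper-quartile factors, with no filter on low counts and under a filter at 1 CPM. Nfe2l2 was lost without empty vector library 2 or either Dnm3os library. Txnrd1 was lost without empty vector library 1 or either Dnm3os library and with a replicate block. DESeq2 called neither gene.

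Of 21 genes of lipid uptake and efflux, 7 rose, 2 fell and 12 did not pass (8 and 3 adjusted over the list alone). The lysosomal cholesterol carrier Npc2 rose from 429 ± 0.479 to 628 ± 6.78 CPM (0.55 ± 0.03), and the lipoprotein lipase Lpl (0.22 ± 0.02), the fatty acid carrier Fabp4 (1.30 ± 0.14) and the cholesterol exporter Abca1 (0.37 ± 0.07) also rose. The exporter Abcg1 (-0.21 ± 0.06) and the phospholipid transfer protein Pltp (-0.15 ± 0.03) fell, Abcg1 not without empty vector library 2 or Dnm3os library 1, nor with isoforms summed. The median was -0.01 while the mean was 0.13 and camera pointed up (adjusted p = 0.199 by camera; adjusted p = 0.0366 by camera without empty vector library 2, over alternatives from 0.0366 to 0.646). The members lower were 5 without empty vector library 1, and 1 without empty vector library 2, without Dnm3os library 1 and with isoforms summed. Of 18 antigen presentation genes, 2 rose, 3 fell and 13 did not pass (3 and 3 adjusted over the list alone). The invariant chain Cd74 rose from 60.6 ± 2.43 to 107 ± 3.62 CPM (0.82 ± 0.04) and H2-DMb1, a class II peptide exchange subunit with similar neighbours, at low counts (1.85 ± 0.60).

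The class I regulator Nlrc5 (-0.29 ± 0.06), H2-T23 (-0.13 ± 0.03) and the class I light chain B2m (-0.11 ± 0.03) fell. The antigen presentation list had a median of -0.04 and a mean of 0.07, and camera pointed down (adjusted p = 0.411 by camera) and up without a filter on low counts (adjusted p = 0.880 by camera; alternatives from -0.874 to 0.880, signed by direction). Leaving out empty vector library 1 gave 1 antigen presentation gene higher and 6 lower, and leaving out Dnm3os library 2 gave 1 higher, as did DESeq2, a filter at 1 CPM and isoforms summed. H2-DMb1 was lost by DESeq2, under a filter at 1 CPM, with isoforms summed, and without empty vector library 1 (1.14) or either Dnm3os library, and was at 3.05 without empty vector library 2; H2-T23 was lost without Dnm3os library 1, and B2m without empty vector library 2 or either Dnm3os library. Gas6, Mfge8, Scarb1, Cd68, Trem2, Nfe2l2, Txnrd1, Abcg1, Pltp and H2-DMb1 were named after their values were seen.

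**Figure D2:**
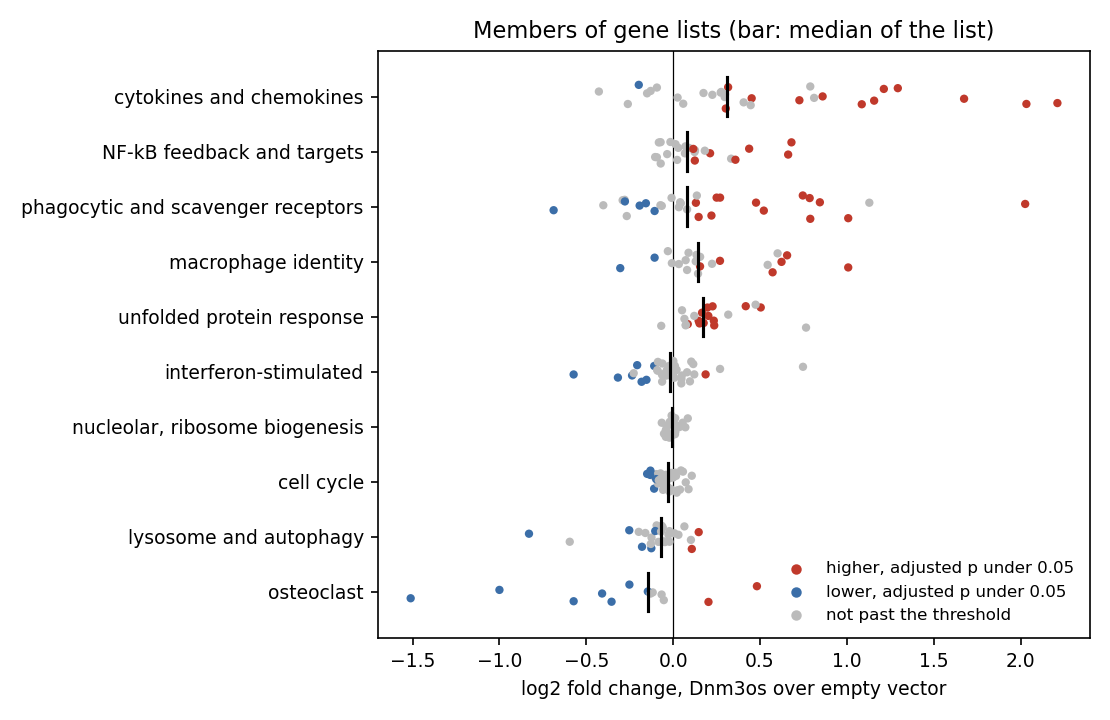
Log2 fold change of Dnm3os over empty vector (2 libraries per group) for each tested member of 10 gene lists, with red points higher, blue points lower and grey points not past the threshold by edgeR; the black bar is the median of the list. Medians run from -0.15 for the osteoclast list to 0.31 for cytokines and chemokines, and the nucleolar genes cluster at 0.

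Genes of the unfolded protein response, which restores folding in the endoplasmic reticulum, were higher by small amounts as a list (adjusted p = 2.51e-07 by camera, and adjusted p = 0.335 with an estimated correlation, over alternatives from 2.00e-08 to 0.335). Of 22 tested, 13 rose, 0 fell and 9 did not pass (18 higher and 1 lower adjusted over the list alone; median 0.17). For the 0 lower, edgeR had 1 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The stress-induced Herpud1 rose from 103 ± 2.05 to 137 ± 0.764 CPM (0.42 ± 0.03) and the chaperone Hspa5 from 2585 ± 27.4 to 2861 ± 5.28 CPM (0.15 ± 0.02), with the folding factors Pdia4 (0.23 ± 0.03) and Sdf2l1 (0.23 ± 0.03). Without Dnm3os library 2, 8 members were higher, and without empty vector library 1, 1 was lower.

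Cholesterol synthesis genes were higher as a list by a small amount (median 0.05; adjusted p = 0.0276 by camera, and adjusted p = 0.335 with an estimated correlation, over alternatives from 0.0254 to 0.335). Of 23 tested, 2 rose, 0 fell and 21 did not pass (2 and 0 adjusted over the list alone), and for the 0 lower edgeR had 0 at an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. The members that rose were the isomerase Idi1 (0.12 ± 0.03) and the reductase Dhcr7 (0.20 ± 0.06), but neither was called by DESeq2 or with isoforms summed, which each gave 0 members higher. The list was lost without empty vector library 1 (adjusted p = 0.0880 by camera) and without Dnm3os library 2 (adjusted p = 0.0990 by camera). In the fits that left out 1 library, 1 cholesterol gene was higher without empty vector library 1, empty vector library 2 or Dnm3os library 1, and 0 were without Dnm3os library 2. Idi1 was lost without empty vector library 2 or either Dnm3os library, and Dhcr7 without empty vector library 1 or either Dnm3os library.

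Osteoclast genes were lower as a list (adjusted p = 0.00114 by camera, and adjusted p = 0.335 with an estimated correlation, over alternatives from -0.335 to -0.00109, signed by direction). Of 13 tested, 2 rose, 7 fell and 4 did not pass (2 higher and 8 lower adjusted over the list alone; median -0.15). Besides Ctsk, the carbonic anhydrase Car2 fell from 207 ± 10.5 to 139 ± 0.213 CPM (-0.57 ± 0.04), the fusion gene Ocstamp from 15.1 ± 0.365 to 7.52 ± 0.921 CPM (adjusted p = 5.28e-08 by edgeR) and the osteoclast transcription factor Nfatc1 from 236 ± 13.7 to 178 ± 0.699 CPM (-0.41 ± 0.04). The gelatinase Mmp9 (0.48 ± 0.05) and Acp5, the acid phosphatase used as an osteoclast stain (0.20 ± 0.06), rose. The call of Acp5 was lost by DESeq2 and with each of the 4 libraries left out in turn, which left 1 member higher in each case.

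Of 26 lysosome and autophagy genes, 2 rose, 5 fell and 19 did not pass (3 higher and 10 lower adjusted over the list alone; median -0.07). The proton pump subunit Atp6v1a fell from 489 ± 24.6 to 410 ± 2.40 CPM (-0.25 ± 0.03), with the subunit Atp6v1h (-0.13 ± 0.03), the transcription factor Mitf (-0.18 ± 0.04), progranulin Grn (-0.10 ± 0.03) and the autophagy gene Wipi1 (-0.83 ± 0.23), and the cathepsins Ctsl (0.15 ± 0.03) and Ctsz (0.11 ± 0.03) rose. Camera gave adjusted p = 0.00838, and adjusted p = 0.575 with an estimated correlation. Signed by direction, the adjusted p was -0.122 without empty vector library 2 and -0.134 by fry, so both lost the call, and the alternatives ran from -0.575 to -0.000447. The members higher were 1 without empty vector library 1 or either Dnm3os library, and the members lower were 9 without empty vector library 1 and 2 without either Dnm3os library, against 3 by DESeq2. Atp6v1h and Grn were lost without empty vector library 2 or Dnm3os library 2, Grn and Mitf without Dnm3os library 1, and Wipi1 and Ctsz without empty vector library 1 or either Dnm3os library; DESeq2 did not call Atp6v1h, Mitf or Wipi1, and Atp6v1h was lost with isoforms summed.

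Of 35 histone and DNA modifiers, 0 rose, 4 fell and 31 did not pass (0 and 4 adjusted over the list alone; median -0.03), and for the 0 higher edgeR had 1 at an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. The deacetylase Hdac5 (-0.17 ± 0.04), the demethylase Kdm5b (-0.47 ± 0.12) and the DNA methyltransferases Dnmt1 (-0.12 ± 0.03) and Dnmt3a (-0.11 ± 0.03) fell, but DESeq2 called 1 member lower and not Hdac5, Kdm5b or Dnmt3a. Camera gave adjusted p = 0.0382, and adjusted p = 0.335 with an estimated correlation. Signed by direction, the alternatives ran from -0.335 to -0.0345. A replicate block also ended the call of the list. The list was lost under a filter at 1 CPM (-0.0506 as adjusted p by camera) and with each library left out in turn, with -0.0851 and -0.0525 for empty vector libraries 1 and 2 and -0.0843 and -0.0990 for Dnm3os libraries 1 and 2. Without Dnm3os library 1 or Dnm3os library 2, 1 modifier was lower. Kdm5b and Dnmt1 were lost without empty vector library 2, Dnmt3a without empty vector library 1, Hdac5, Dnmt1 and Dnmt3a without Dnm3os library 1, and Kdm5b, Dnmt1 and Dnmt3a without Dnm3os library 2.

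Extracellular matrix genes moved both ways. Of 15 tested, 3 rose, 4 fell and 8 did not pass (4 and 4 adjusted over the list alone; median 0.07; adjusted p = 0.711 by camera). Mmp12 and Mmp9 rose, and Mmp8, the neutrophil collagenase, was called higher with counts of 1 and 0 against 11 and 13. The collagen chain Col18a1 (-1.11 ± 0.12), the laminin chain Lamc1 (-0.22 ± 0.04) and urokinase Plau (-0.22 ± 0.04), which DESeq2 did not call, were among those that fell. Fry called the list up (adjusted p = 0.0159 by fry), while camera pointed down under a filter at 1 CPM (-0.426) and without Dnm3os library 2 (-0.631), with alternatives from -0.631 to 0.735 as adjusted p signed by direction. Acp5, Atp6v1h, Wipi1, Ctsz, Mmp8, Lamc1 and Plau were named after their values were seen.

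**Figure D3:**
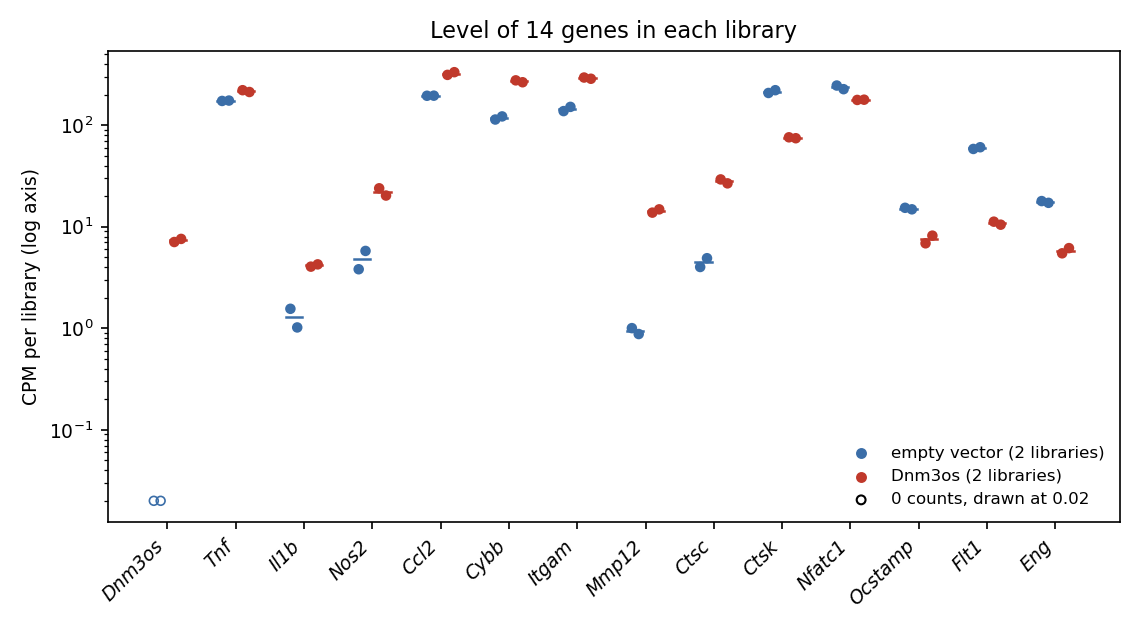
CPM in each library on a log axis for 14 genes, with blue points for empty vector and red points for Dnm3os (2 libraries each), lines at the group means and open points for 0 counts, drawn at 0.02. For each of the 14 genes the points of the groups do not overlap, as for all 1616 called genes, to which these belong. Ctsk, Nfatc1, Ocstamp, Flt1 and Eng are lower and the others higher in Dnm3os.

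Nucleolar and ribosome biogenesis genes showed no call. Of 27 tested, 0 rose, 0 fell and 27 did not pass (0 and 0 adjusted over the list alone), edgeR had 1 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The nucleolar protein nucleolin, Ncl, and the RNA-binding Ilf2, both fixed as named genes, were at 2591 ± 32.9 against 2662 ± 1.05 CPM (log2 fold change -0.04 ± 0.02; adjusted p = 0.256 by edgeR) and 163 ± 0.941 against 155 ± 3.99 CPM (0.07 ± 0.03; adjusted p = 0.184 by edgeR). The median was -0.01 and camera pointed down (adjusted p = 0.753 by camera), but up without Dnm3os library 1 (adjusted p = 0.873 by camera; alternatives from -0.837 to 0.873, signed by direction).

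Of 36 cell cycle genes, 0 rose, 5 fell and 31 did not pass (0 and 5 adjusted over the list alone; median -0.03; adjusted p = 0.0802 by camera). For the 0 higher, edgeR had 2 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The topoisomerase Top2a fell from 580 ± 3.31 to 523 ± 10.9 CPM (-0.15 ± 0.03), with the proliferation marker Mki67 (-0.11 ± 0.03), the replication clamp Pcna (-0.10 ± 0.03), the kinetochore gene Cenpf (-0.13 ± 0.04) and the transcription factor E2f1 (-0.13 ± 0.04), which was named after its value was seen. The list passed without empty vector library 2 (-0.0333 as adjusted p by camera signed by direction, over alternatives from -0.575 to -0.0333). The fit without empty vector library 1 called 1 member higher; 2 were lower without empty vector library 1, without empty vector library 2 and without Dnm3os library 2, and 1 without Dnm3os library 1. DESeq2 called 3 lower, without Cenpf and E2f1, and 3 were lower with isoforms summed, without Cenpf and Pcna. Pcna was lost with each library left out in turn, Mki67 without empty vector library 1 or either Dnm3os library, Cenpf without empty vector library 2 or either Dnm3os library, and E2f1 by limma-voom and without either empty vector library or Dnm3os library 1.

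Of 25 genes of glycolysis and hypoxia, 1 rose, 3 fell and 21 did not pass (1 and 4 adjusted over the list alone; median -0.04; adjusted p = 0.116 by camera). The aldolase Aldoc (-0.26 ± 0.04), the pyruvate dehydrogenase kinase Pdk1 (-0.15 ± 0.04) and the lactate carrier Slc16a3 (-0.11 ± 0.03) fell, and the phosphofructokinase Pfkp rose (0.13 ± 0.03). The list passed without Dnm3os library 1 (-0.0226 as adjusted p by camera signed by direction, over alternatives from -0.770 to -0.0226). Without empty vector library 1, 0 members were higher and 7 lower, without Dnm3os library 1, 0 were higher, and without Dnm3os library 2, 2 were higher and 1 lower; without empty vector library 2, 2 were higher. DESeq2 called 0 higher and 1 lower, as did the fit with isoforms summed, and both lost Pfkp, Pdk1 and Slc16a3. Pfkp was lost without empty vector library 1 or Dnm3os library 1, Slc16a3 without empty vector library 2 or Dnm3os library 2, and Pdk1 without Dnm3os library 2.

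Across the 20 lists tested, camera with a preset correlation called 9, 6 up and 3 down, fry called 10, and 8 were called by both. With an estimated correlation camera called 0, and 0 lists had an unadjusted p under 0.05. That setting rests on the few residual degrees of freedom of 4 libraries, so it can call little whatever the correlation. The osteoclast, cholesterol synthesis and histone modifier lists had estimates of -0.0369, -0.0405 and -0.0267. These lie below the preset 0.01, and the osteoclast p still went from 0.000228 to 0.0599 by camera. Estimates were higher for unfolded protein response (0.2169) and lysosome genes (0.4304). Markers of other cell types were scarce: of 67 markers of B, T and NK cells, fibroblasts, epithelium, dendritic cells, and granulocytes and mast cells, 9 were expressed enough to test. EdgeR called 0 of these 9, with 2 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The granulocyte gene S100a8 had the highest log2 fold change (0.34 ± 0.13) and the T cell kinase Lck the lowest (-0.34 ± 0.11, adjusted p = 0.0513 by edgeR). The summed CPM of the T and NK cell markers differed by -1.79 ± 0.201 (SE) in Dnm3os against empty vector.

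The libraries of a group resembled each other more than those of the other group. Pearson's r across genes, which are not independent replicates, was 0.996 between the empty vector libraries, 0.9955 between the Dnm3os libraries and 0.9897 to 0.9908 between groups. The root mean square log2 difference was 1.52 ± 0.0534 times as large between groups as within them (SD over the pairs of replicates). The first principal component held 64.6% of the variance and parted the groups. With 2 libraries per group no permutation test can reach a p of 0.05, so this is a description with no test.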

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

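The tests of other lineages, of a difference between the lines, of the small nucleolar RNAs and of neighbours without gene families were chosen only after the result was seen. Mir214, a microRNA gene inside Dnm3os that the main comparison did not test, had 7 counts over both Dnm3os libraries against 0 in both empty vector libraries, and was flagged for this. With no filter on low counts, 3 genes of the locus were tested and 1, Dnm3os, was called. Since Mir214 lies inside Dnm3os, its counts cannot be told apart from reads of the Dnm3os transcript.

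The cytokine and chemokine list was higher in Dnm3os, with a median log2 fold change of 0.31 over 30 tested members (adjusted p = 2.51e-07 by camera, and adjusted p = 0.335 with an estimated correlation, over alternatives from 3.71e-09 to 0.335). GC content and transcript length as the cause are argued against, since among 10000 random lists matched on expression, GC content and length the list's median lay at percentile 100.00. Cells of 6 other lineages in the Dnm3os libraries were weighed as the source of the list's summed gain. The 12 members that rose gained 431 CPM, and the summed markers of a lineage, tested or not, at most 2.92 CPM. That value is the fibroblast difference of 0.881 plus 2 SE, under the bound of 1% of the gain. Ccl9 (570 to 779 CPM) and Ccl2 (195 to 322 CPM) made up much of the gain. The bound, 4.31 CPM, exceeds the whole rise of a low member such as Il1b (1.29 to 4.15 CPM), so for such members the test cannot decide. How much cytokine RNA such cells carry per marker count was not measured. The granulocyte and mast cell sum was 0.950 ± 0.395 (SE) CPM higher, with S100a8 at 0.34 ± 0.13 (adjusted p = 0.092 by edgeR) and its partner S100a9 at 0 counts in all 4 libraries. A difference between the stable lines that is unrelated to Dnm3os cannot be told apart from an effect of Dnm3os, since each plasmid stands for 1 line as far as the labels say, and the ratio of between-group to within-group difference of 1.52 is what either would give. An effect of Dnm3os on these genes remains a hypothesis.

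Counts at the small nucleolar RNA genes Snora41 and Gm12238 were lower in Dnm3os. They were 1891 and 1705 against 17 and 18 for Snora41, and 241 and 217 against 1 and 1 for Gm12238. Gm12238 was named after its values were seen. The libraries hold poly(A) RNA, and counts per gene do not separate reads of a small RNA from reads of the host intron. Lower transcription of the host genes is argued against by the lower of the host log2 fold changes, -0.01 for Eef1b2 (± 0.03), with G3bp1 at 0.01 (± 0.03). Lower recovery of small RNAs in the Dnm3os libraries is argued against by a median of 0.01 over the 104 other tested snoRNA and scaRNA genes (-0.48 to 0.82). Of these edgeR called 0, with 2 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The argument holds only as far as counts at these genes come from small RNAs. A DNA change in the host introns of 1 line, unrelated to Dnm3os, may account for the falls and was not tested, and neither was an effect of Dnm3os on these RNAs. The unrelated predicted gene 1810010D01Rik, chosen after its values were seen, had 45 and 38 counts against 0 and 0.

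Genes changed at least 2-fold lay beside each other more often than in shuffles of the tested genes. Of 13101 adjacent pairs, 25 changed the same way, against a mean of 2.27 and a 95th percentile of 5 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). Reads shared between neighbouring paralogs or overlapping genes account for some of these pairs. Gm13305 and Il11ra2, named after their values were seen, had identical counts in every library. Shuffling parts such copies, so the first permutation p overstates the evidence. Without pairs of a family, pairs of zinc finger or predicted genes, overlapping pairs and pairs with identical counts, 8 remained (mean 1.80, 95th percentile 4, permutation p = 5e-04). The shuffles behind both counts did not match genes on expression level, so they cannot show what genes of like level would give. The 8 pairs, among them Lst1 with Ltb and Crybg2 with Cd52 (named after their values were seen), could share a chromatin or DNA change of 1 line or reads that run from a gene into the next, and neither was tested.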

How the results depend on the processing

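Isoforms summed and the authors' scaling constants were chosen after the data were seen; all other alternatives were planned. Of 93 named genes with alternatives, 73 kept their direction and their side of the threshold under all of them, 20 lost their call under at least 1, and 0 were reversed; no called gene shared with another setting changed sign. DESeq2 called fewer genes (404 higher and 362 lower; 98 and 40 at least 2-fold), 760 of its 766 calls shared with edgeR; the cause was not tested. The filter at 1 CPM left 102 genes at least 2-fold higher, with fewer genes tested. Leaving out 1 library, with fewer libraries in the fit, gave 465 to 808 genes higher and 396 to 786 lower, lowest without Dnm3os library 2 and, below the main count by over 1.5 times, also without Dnm3os library 1 (492 and 455). Lists called were 0 with an estimated correlation, 10 by fry, and 5 (without empty vector library 1) to 10 (without empty vector library 2) with 1 library left out. The separation ratio was 1.22 with no filter, 1.79 at 1 CPM, 1.45 with isoforms summed and 1.37 (without empty vector library 2) to 1.53 (without Dnm3os library 2) with 1 library left out; the cause was not tested. Direction reversed, as camera's adjusted p signed by direction and past no threshold, for antigen presentation with no filter (0.880; range -0.874 to 0.880), extracellular matrix at 1 CPM (-0.426) and without Dnm3os library 2 (-0.631, against up to 0.569 without Dnm3os library 1; range -0.631 to 0.735), and nucleolar genes without Dnm3os library 1 (0.873, against -0.805 without empty vector library 1; range -0.837 to 0.873); the cause was not tested. A replicate block, for numbers that may share nothing but a number (correlation of deviations -0.0634), gave 868 higher and 782 lower with 1530 of 1650 calls shared and 8 lists, with histone modifiers at -0.0763 (range -0.335 to -0.0345). It lost 86 of the reported calls, among them Nos2 (log2 fold change 2.21) and Txnrd1. Under the other scalings 1594 to 1653 genes were called, and limma-voom called 1591, of which 1545 were shared. Camera was not run on the DESeq2 and limma-voom fits, and a pseudocount on normalized values did not apply. Depth limits genes at few counts: Mir214, Mir199a-2 and Il6 lay below the filter of the reported fit.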

Other observations

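All genes of this part were chosen after their values were seen, and no test of an explanation was run here. The genes named here as higher or lower were called by edgeR and under all 14 alternatives tried. Among genes in no fixed list, the TNF family ligand Tnfsf14 rose from 0.630 ± 0.110 to 5.83 ± 0.504 CPM (SD, n = 2 per group; log2 fold change 3.22 ± 0.19, SE) and the growth factor Igf1 from 1.18 ± 0.289 to 6.27 ± 0.834 CPM (2.42 ± 0.18). The adaptor Stap1 rose from 37.7 ± 1.66 to 120 ± 1.85 CPM (1.67 ± 0.04), and Acod1, which makes itaconate in activated macrophages, from 25.4 ± 2.19 to 64.7 ± 0.364 CPM (1.35 ± 0.06). The siderophore-binding Lcn2 (1.49 ± 0.12), the complement receptor C5ar1 (1.59 ± 0.16), the chemokine receptor Ccr1 (0.75 ± 0.06), the TNF receptor Tnfrsf1b (0.99 ± 0.06) and the RNA-binding Zfp36l1 (2.99 ± 0.21) were also higher. The paralogs Xlr3b and Xlr3c, whose reads may be shared, had larger rises from few counts. Xlr3b went from 0.0785 ± 0.0309 to 2.49 ± 0.135 CPM (4.90 ± 0.37) and Xlr3c from 0.0910 ± 0.0486 to 3.565 ± 0.628 CPM (5.20 ± 0.35). Their paralog Xlr3a was also higher, from counts near the floor. The genes named are a choice and not a ranking.

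Among genes that fell, the hypoxia factor Epas1 went from 1.44 ± 0.161 to 0.197 ± 0.134 CPM (-2.80 ± 0.39; -3.77 without Dnm3os library 2 and -2.29 without Dnm3os library 1) and the microtubule genes Map6 and Kif21a from 6.78 ± 0.0157 to 0.942 ± 0.0128 CPM (-2.84 ± 0.16) and from 7.09 ± 0.267 to 1.06 ± 0.0629 CPM (-2.73 ± 0.16). The caveolar gene Cavin1 (-2.10 ± 0.24) and the semaphorin receptor Plxna4 (-1.05 ± 0.05) were lower too.

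The class I genes of the H2-Q region varied between libraries of a group. H2-Q2 was at 797 and 324 CPM in empty vector libraries 1 and 2 and at 107 and 441 CPM in Dnm3os libraries 1 and 2, and the sum over 7 H2-Q genes was 5197 and 3449 CPM in the former and 2812 and 4204 CPM in the latter, higher in library 1 of the empty vector group and in library 2 of the Dnm3os group. These genes share much of their sequence, so their reads are uncertain, and edgeR called 0 of the 7, with 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0, with 1 at that level by DESeq2 and 0 by limma-voom.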
